A study of Mus musculus with 30 samples.

How the data were processed

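Poly(A) RNA was measured in RGC and non-RGC fractions of newborn mouse retina, separated with anti-CD90 magnetic beads, per the labels' protocols. Libraries were made with the NEBNext poly(A) kit and read as single reads of 75 cycles, per the series' design text. Per the submitters' processing notes, the RNA reads were handled with STAR 2.3, featureCounts, DESeq and FastQC on genome build mm10. The notes give no other version for these tools and no strand setting, so it is unknown whether reads of overlapping antisense genes were separated. The names of the deposited tables show that alignments were sorted, limited to primary alignments and cleared of duplicates before counting. For single reads, duplicate removal limits the reads that can start at a position, so counts of short abundant transcripts saturate and their fold changes shrink.

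The 2 tables hold the authors' comparisons, each listing 38720 gene symbols with 7 columns of values. Per the file headers, these are the deposited mean normalised count over all libraries and over each of the conditions A and B, the deposited fold change as a ratio of B to A, its log2 value, the p-value and the adjusted p-value of the authors. The authors' p-values come from the DESeq test named in the processing notes and their adjusted p is the Benjamini-Hochberg value over all genes with a p. Neither table lists values per library. Which condition is A or B was settled from genes with a mean of 0. Condition A of the table of fractions and condition B of the table of genotypes were at 0 in the same 14765 genes with no mismatch, so both are the mutant RGCs, while every other pairing had at least 3098 mismatches. The labels hold 2 mutant genotypes, both with floxed Ezh2 and 1 of them with a floxed copy of Ehmt2 as well. The tables do not say which was used, and it was not inferred from expression.

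Counts per library were recovered from the deposited means. A mean of 3 libraries is the sum of 3 whole read counts, each divided by 3 times that library's size factor. The 3 smallest values above 0 in a condition, 1 read in 1 library each, gave the size factors, and a search over whole numbers then gave each gene's 3 counts. A solution was taken where the last count lay within 1e-09 of a whole number and the next best combination lay more than 10 times further off. This held for between 99.975% and 100.0% of the genes above 0 in a condition, and the best solution of any gene lay within 1.3e-10. The mutant RGC counts, recovered from each table on its own, were identical for all 23953 genes compared. Size factors recomputed from the recovered counts as medians of ratios differed from those of the steps by at most 0.0083%. In simulated data all 2348 genes above 0 were recovered. Ank2, Kif1b, Reln, Adcy1, Map1b and Dync1h1, abundant genes with more than 1 solution in WT, were left out of the comparison of genotypes. The recovered libraries carry no sample numbers, so they were numbered within each group by size factor and cannot be tied to single samples.

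The planned test for normalised values per library was used. Recovered counts were divided by the authors' size factors, genes with a mean of at least 10 over the 6 libraries of a comparison were kept, and limma 3.58.1 with a variance trend (R 4.3.3) was fitted to log2(value + 1) of those 6 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale and understate changes of low genes. Means and SDs are of the normalised counts of 3 libraries. Comparisons across all 9 libraries used median-of-ratios factors computed over the 9. The counts were recovered and not read from a count table, so a count model was not the main test, and voom weights on the recovered counts were run as an alternative.

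Before the data were examined, 32 lists with 677 genes were written, of which 669 genes are in the tables and 4 stand in more than 1 list. They cover the targets, chromatin regulators, developmental genes, markers of retinal and other cell types, and cell states. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The naming rule, also fixed then, takes Ezh2, Ehmt2 and Atoh7, the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 50 and no overlap between the groups, passing over predicted genes, clone names and pseudogenes, and up to 3 members of each list with the smallest adjusted p. Some genes that this rule names are not reported. Symbols were used as the tables give them, and 35654 of them matched the gene name table. Coordinates are those of RefSeq genes on GRCm38, the assembly also called mm10.

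On simulated counts drawn from the real means, with 200 changed genes, limma called 16 of 67 genes changed 1.5-fold, 39 of 65 changed 2-fold and 55 of 65 changed 4-fold, with no false call, for the 15256 genes of the genotype comparison. For the fractions (15143 genes) it called 32, 41 and 59 of 66 each, with 8 false calls. Camera called 50 of 50 simulated lists shifted 1.5-fold in each comparison, and of 50 unshifted lists it called none for the genotypes and 1 for the fractions. These simulated genes varied independently of each other.

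Alternatives were other pseudocounts, filters, thresholds and scalings, voom, the authors' own calls, each library left out in turn and, for lists, other forms of camera. The alternatives written for deposited counts were not run. The chromatin samples, the WT non-RGC libraries and the RNA libraries of the genotype not in the tables were not analysed here. Python 3.11.15 with numpy 2.4.6, numba 0.67.0 and matplotlib 3.10.9 was used for count recovery and plots.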

Results

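Retinas of newborn mouse pups were digested with papain, and retinal ganglion cells (RGCs), the neurons whose axons form the optic nerve, were drawn from the suspension with magnetic beads against CD90, the surface protein encoded by Thy1. The cells left behind formed the non-RGC fraction. The series compares mice in which Cre recombinase under Math5 (Atoh7) control, active in the ganglion cell lineage, is meant to remove floxed Ezh2, alone or together with 1 floxed copy of the G9a gene Ehmt2, with C57BL/6 wild type (WT) mice. Ezh2 is the catalytic subunit of Polycomb repressive complex 2 and methylates histone H3 at lysine 27. G9a methylates the same histone at lysine 9. Poly(A) RNA was sequenced from 3 libraries per genotype and cell fraction, 18 libraries in all, and 12 further samples were chromatin immunoprecipitations or inputs that were not analysed here. The deposited tables cover 9 of the RNA libraries, namely 3 of WT RGCs, 3 of mutant RGCs and 3 of mutant non-RGC cells. They call the mutant only "mut", so its genotype, with or without the floxed copy of Ehmt2, is left open, and mutant below means the libraries so named.

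The 9 libraries held between 10551825 and 12259494 assigned reads after duplicate removal, and between 19870 and 21665 genes had at least 1 read. The 10 most abundant genes took between 0.675% and 0.781% of the reads and mitochondrially encoded genes between 0.126% and 0.138%. Duplicate removal limited the counts of short abundant transcripts. The mitochondrial mt-Co1 had between 1648 and 1721 reads in all 9 libraries, an SD of 20.4 around a mean of 1688.6 where counting error alone would give 41.1, so fold changes of such genes are compressed. No library was identified by a replicate number in the tables, and libraries are numbered 1 to 3 within a group by falling size factor, with no pairing between groups. Nothing in the labels says whether the 3 libraries of a group came from separate animals or pools, so p-values measure the spread between these libraries. Pairs of libraries within a group differed by more than counting error, with a mean chi-square per gene between 1.88 and 21.01.

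Ezh2 (chromosome 6, 47530274 to 47595270, GRCm38) was higher, not lower, in the libraries labelled mutant RGC than in WT RGCs. Its normalised count was 1289 ± 242 (SD, n = 3) in WT and 1906 ± 48.9 (SD, n = 3) in mutant RGCs, a log2 fold change of 0.58 (SE 0.13, limma adjusted p = 0.0292). Ehmt2 (chromosome 17, 34898463 to 34914073) was lower in the mutant RGCs, at 2753 ± 362 (SD, n = 3) against 3702 ± 143 (SD, n = 3), a log2 fold change of -0.43 (SE 0.11, limma adjusted p = 0.0332). Atoh7 (chromosome 10, 63099785 to 63101280), the gene whose control elements drive the Cre, had 144 ± 112 (SD, n = 3) in WT and 299 ± 98.2 (SD, n = 3) in mutant RGCs, which did not pass the test (limma adjusted p = 0.113). In the mutant non-RGC libraries Ezh2 was 1.19-fold above mutant RGCs (log2 0.25, SE 0.06, limma adjusted p = 0.0242), a call that the authors' deposited table does not make (adjusted p = 0.4072), while Ehmt2 (log2 0.15, SE 0.11) and Atoh7 (log2 0.28, SE 0.29) did not pass (limma adjusted p = 0.402 and 0.565). The tables count reads over the whole gene, and transcripts that lack the floxed exons still count. Which exons are floxed is not given in the sources used here, so these values check neither the deletion nor the labels. Like the proliferation genes described below, Ezh2 was higher in WT library 3 (1568) than in WT libraries 1 and 2 (1144 and 1154). A different mix of cells was not told apart from a change of Ezh2 within ganglion cells. Against WT, the Ezh2 call was lost without WT library 1 or 2 (limma adjusted p = 0.1169 and 0.1020) or mutant RGC library 1, 2 or 3 (0.0554, 0.0765 and 0.0695), and the Ehmt2 call without WT library 1 or 2 (0.1238 and 0.1006) or mutant RGC library 2 or 3 (0.0749 and 0.0670). Between the fractions, the Ezh2 call was lost without mutant RGC library 2 or 3 (0.0991 and 0.1151) or non-RGC library 1 or 2 (0.0907 and 0.0543).

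The comparison of mutant with WT RGCs asks how the bead-selected cells of mice labelled mutant differ from those of WT mice. In the mutant RGC libraries 14 of 32 ganglion cell markers and 16 of 38 synaptic genes were lower, while 34 of 38 proliferation genes, 9 of 32 progenitor and Mueller glia markers and 8 of 28 photoreceptor markers were higher. Camera called these lists at a preset correlation and none of them with an estimated correlation (adjusted p = 0.7307 for each). Of the 15276 genes tested, 3971 changed at a limma adjusted p under 0.05, 2092 higher and 1879 lower, and 462 of the former and 660 of the latter changed by more than 2-fold. The 2 groups did not overlap for 51.1% of the tested genes, where chance gives 10% on average over splits of the 6 libraries. Genes vary together between libraries, so a single split can lie far from this average.

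Among 32 ganglion cell markers, 14 fell and 2 rose, with a median log2 fold change of -0.76. The heavy neurofilament gene Nefh fell from 518 ± 155 to 157 ± 13.2 (SD, n = 3 each; log2 -1.67, SE 0.24, limma adjusted p = 0.0225). The nicotinic receptor subunit gene Chrna6 fell from 2046 ± 337 to 824 ± 296 (log2 -1.37, SE 0.29) and Nrn1, which encodes the neurite growth factor neuritin, from 1145 ± 75.5 to 530 ± 180 (log2 -1.17, SE 0.26). Thy1, whose product the beads bind, fell by 0.80 on the log2 scale (limma adjusted p = 0.0305). It and the next 2 genes lie outside the naming rule and were chosen after their values were seen. The members that rose were the homeobox genes Dlx1 (log2 1.32) and Dlx2 (log2 1.23), which act in developing ganglion and amacrine cells. Adjusted over the list alone, 26 markers fell and 2 rose. Among 38 synaptic genes, 16 fell and 3 rose (31 and 3 adjusted over the list alone), with a median of -0.60. Syn2, which encodes a synaptic vesicle protein, fell from 1222 ± 412 to 358 ± 80.6 (log2 -1.73, SE 0.30, limma adjusted p = 0.0242), and Snap25, which encodes a vesicle fusion protein, by 0.44. The adhesion gene Nlgn1 rose by 0.61. Camera placed the lists below other genes (adjusted p = 2.32e-06 for ganglion and 4.36e-06 for synaptic genes). Neither call held with an estimated correlation (adjusted p = 0.7307 for each list).

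Proliferation genes rose almost throughout. Of 38 members, 34 rose and none fell (37 adjusted over the list alone), with a median log2 fold change of 0.95 and a camera adjusted p of 2.98e-12 (adjusted p = 0.7307 with an estimated correlation). Cenpf, a kinetochore gene of dividing cells, rose from 1353 ± 428 to 3246 ± 47.9 (SD, n = 3 each; log2 1.31, SE 0.20, limma adjusted p = 0.0237), Cenpe by 1.15 and the mitotic kinase gene Plk1 by 1.13 on the log2 scale. Of 32 progenitor and Mueller glia markers, 9 rose and none fell (18 rose and 1 fell adjusted over the list alone; median 0.54, camera adjusted p = 9.51e-06). Olig2, a basic helix-loop-helix gene of retinal progenitors, rose from 242 ± 117 to 727 ± 33.5 (log2 1.68, SE 0.30), and the glutamate transporter gene Slc1a3 by 0.92. Of 28 photoreceptor markers, 8 rose and none fell (12 adjusted over the list alone; median 0.61, camera adjusted p = 8.84e-05). Thrb, which encodes a thyroid hormone receptor of cones, rose from 336 ± 119 to 889 ± 47.7 (log2 1.46, SE 0.23), the cone opsin gene Opn1sw by 1.13 and the cone phosphodiesterase gene Pde6h by 1.17. With an estimated correlation the adjusted p was 0.7307 for the progenitor list and the photoreceptor list alike. Amacrine cell markers went both ways, 8 of 20 higher and 3 lower (the same numbers adjusted over the list alone), and camera did not call the list (adjusted p = 0.1539). Gad1, which encodes an enzyme of GABA synthesis, rose by 0.59 and the transcription factor genes Tfap2b and Tfap2c by 0.75 and 0.92. WT library 3 lay between the other WT libraries and the mutant RGCs in mean level of the proliferation and progenitor lists. Its mean proliferation level, relative to the mean of the 9 libraries, was -0.164 on the log2 scale, against -0.98 and -0.894 in WT libraries 1 and 2 and between 0.181 and 0.219 in mutant RGCs. Mutant RGC library 1 had the lowest ganglion cell level of the mutant RGCs, -0.078 against 0.653 and 0.629, and the highest photoreceptor level, 0.693 against -0.162 and -0.085.

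**Figure D1:**
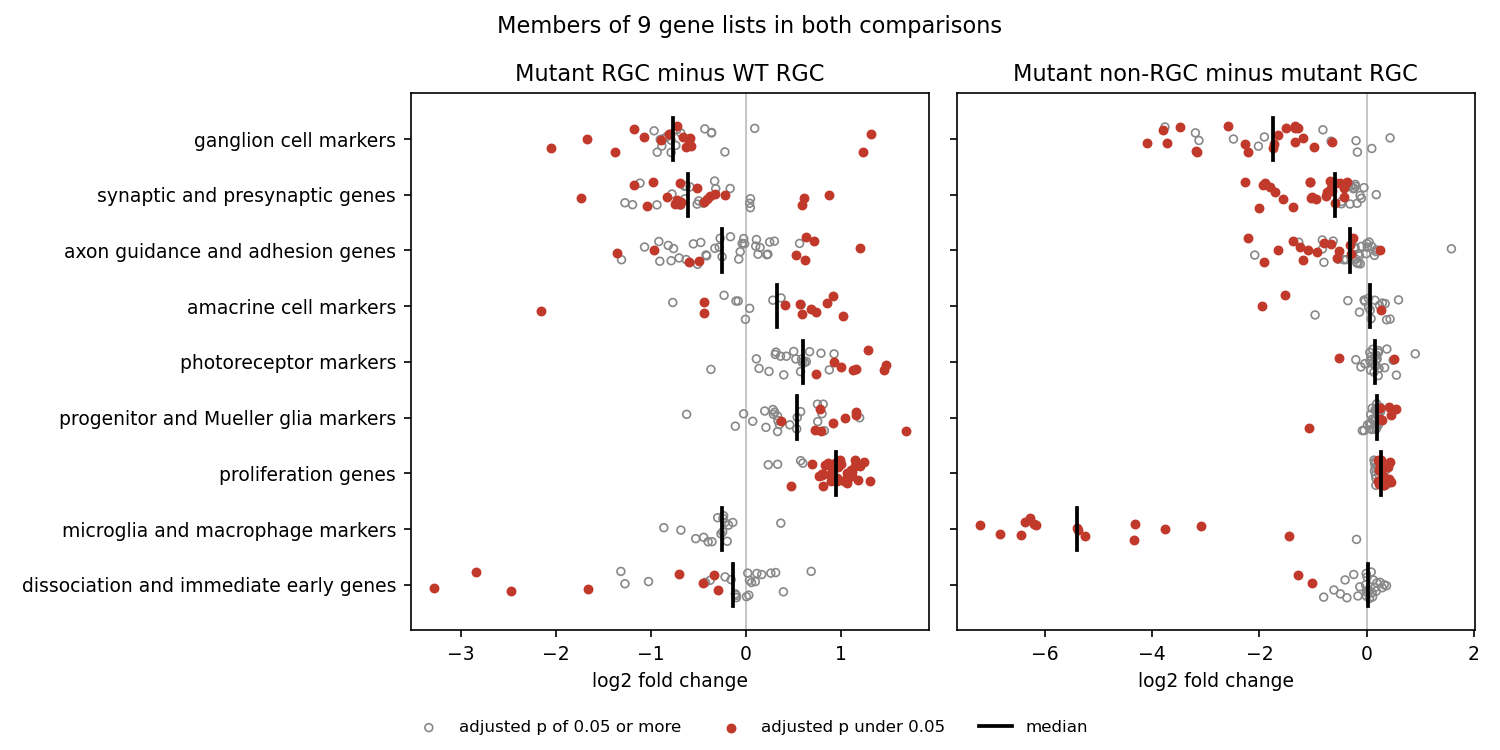
Each point is the log2 fold change (x axis) of 1 member of a gene list (rows), for mutant minus WT RGCs on the left and mutant non-RGC minus mutant RGC on the right. Filled points have a limma adjusted p under 0.05 and black bars are list medians, which run from -0.76 for ganglion cell markers to 0.95 for proliferation genes on the left and reach -5.40 for microglia markers on the right.

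Of 10 tested members of Polycomb repressive complex 2, 2 were higher and 1 lower (6 and 2 adjusted over the list alone). Suz12, a core subunit, rose by 0.58 on the log2 scale and the accessory subunit genes Aebp2 and Phf1 changed by 0.34 and -0.71. Of 19 members of Polycomb repressive complex 1, 2 were higher and 2 lower (2 and 1 adjusted over the list alone), among them Pcgf5 at 1.03 and Cbx6 at -0.50. Camera called neither list (adjusted p = 0.2432 and 0.7485). Of 19 other chromatin methylation enzymes, 7 rose and none fell (9 adjusted over the list alone; camera adjusted p = 0.0145, and adjusted p = 0.7307 with an estimated correlation), including the lysine 27 demethylase gene Kdm6a at 0.46, Kdm3a at 0.36 and the DNA methyltransferase gene Dnmt3b at 0.84. Without WT library 3 that list was not called (adjusted p = 0.0872). None of the 39 Hox genes, classical Polycomb targets, reached the mean normalised count of 10 needed for testing, in either comparison. Of 56 other developmental regulators under Polycomb control, 16 were tested, and 3 rose and none fell (3 adjusted over the list alone; camera adjusted p = 0.1539). They were Gbx2 (31.2 ± 6.48 to 79.6 ± 4.65, SD, n = 3 each), Olig1 (7.30 ± 2.11 to 25.9 ± 11.7) and Olig2, which is also a progenitor marker.

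The 8 largest decreases under the naming rule included Rec8, which encodes a meiotic cohesin subunit, and 3 transcription factor genes that neuronal activity or dissociation can induce. Rec8 fell from 204 ± 10.1 to 10.5 ± 0.533 normalised counts (SD, n = 3 each; log2 -4.15, SE 0.18, limma adjusted p = 0.0017), and its log2 difference between the mutant fractions was 0.48 (SE 0.34, limma adjusted p = 0.3763). Nr4a3 fell from 1347 ± 611 to 133 ± 48.1 (log2 -3.28, SE 0.45), Fosl2 from 1324 ± 608 to 168 ± 1.91 (log2 -2.84, SE 0.36) and Npas4 from 2007 ± 273 to 370 ± 118 (log2 -2.47, SE 0.22). Ptchd4, Plekhg4, the somatostatin receptor gene Sstr1 and the G protein regulator gene Rgs11 completed the 8, with log2 fold changes between -2.58 and -2.25. In the list of dissociation and immediate early genes, 8 of 30 fell and none rose (8 adjusted over the list alone), including Nr4a1 at -1.66 and the heat shock cognate gene Hspa8 at -0.70, with a median over all members of -0.13 (camera adjusted p = 0.0145, and adjusted p = 0.7307 with an estimated correlation). That list was not called without WT library 3 (adjusted p = 0.2873) or mutant RGC library 2 (adjusted p = 0.0520). Differences in handling of the cells between WT and mutant preparations were not told apart from the genotype. Among the largest increases, Hes2, a basic helix-loop-helix gene, rose from 32.8 ± 25.5 to 175 ± 56.9 (log2 2.57, SE 0.54) and the noradrenaline transporter gene Slc6a2 from 35.3 ± 7.61 to 165 ± 71.9 (log2 2.13, SE 0.34). The protease gene Prss56, Frem2, the linker histone gene Hist1h1e, the recombinase gene Rag1 and the chromatin protein gene Hmga2 rose by between 1.81 and 2.05.

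Among 30 genes of p53 signalling, cell death and axon injury, 6 rose and 5 fell (7 and 8 adjusted over the list alone), with Gadd45b at -1.41, Cdkn1a at -0.85 and Trp53inp1 at 0.88 (camera adjusted p = 0.4269). Of 43 axon guidance and adhesion genes, 5 rose and 4 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.3679), with the semaphorin receptor gene Nrp2 at -0.97, the netrin receptor gene Unc5a at -0.49 and Sema5a at 0.72. Of 16 histone genes 3 rose (1 adjusted over the list alone; camera adjusted p = 0.0129, and adjusted p = 0.7721 with an estimated correlation), among them Hist1h1c at 1.27. None of the 8 astrocyte markers changed singly, though camera called the list higher (median 0.60, adjusted p = 0.0249, and adjusted p = 0.7307 with an estimated correlation), a call lost without WT library 3 (adjusted p = 0.0629) or mutant RGC library 1 (adjusted p = 0.0549). None of 16 microglia markers passed (median -0.25, camera adjusted p = 0.4643), but without mutant RGC library 1, whose microglia level was the highest, 8 fell (median -1.01, camera adjusted p = 4.30e-06).

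The authors' deposited table of this comparison called 3024 genes at an adjusted p under 0.05, 1381 higher and 1643 lower. Of these, 2683 were also called here, all 2683 in the same direction. The counts used here come from the same deposited means and size factors, so the shared direction was nearly assured. Scaling turned the majority of the limma calls, with 1980 higher and 2293 lower under upper-quartile scaling and 2396 higher and 1902 lower under total-count scaling. The number of calls depended on single libraries. Limma called 9 genes without WT library 1, 8 without WT library 2, 6478 without WT library 3, 2284 without mutant RGC library 1, 3 without mutant RGC library 2 and 9 without mutant RGC library 3, and only 10 genes had an adjusted p under 0.01 with all libraries.

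**Figure D2:**
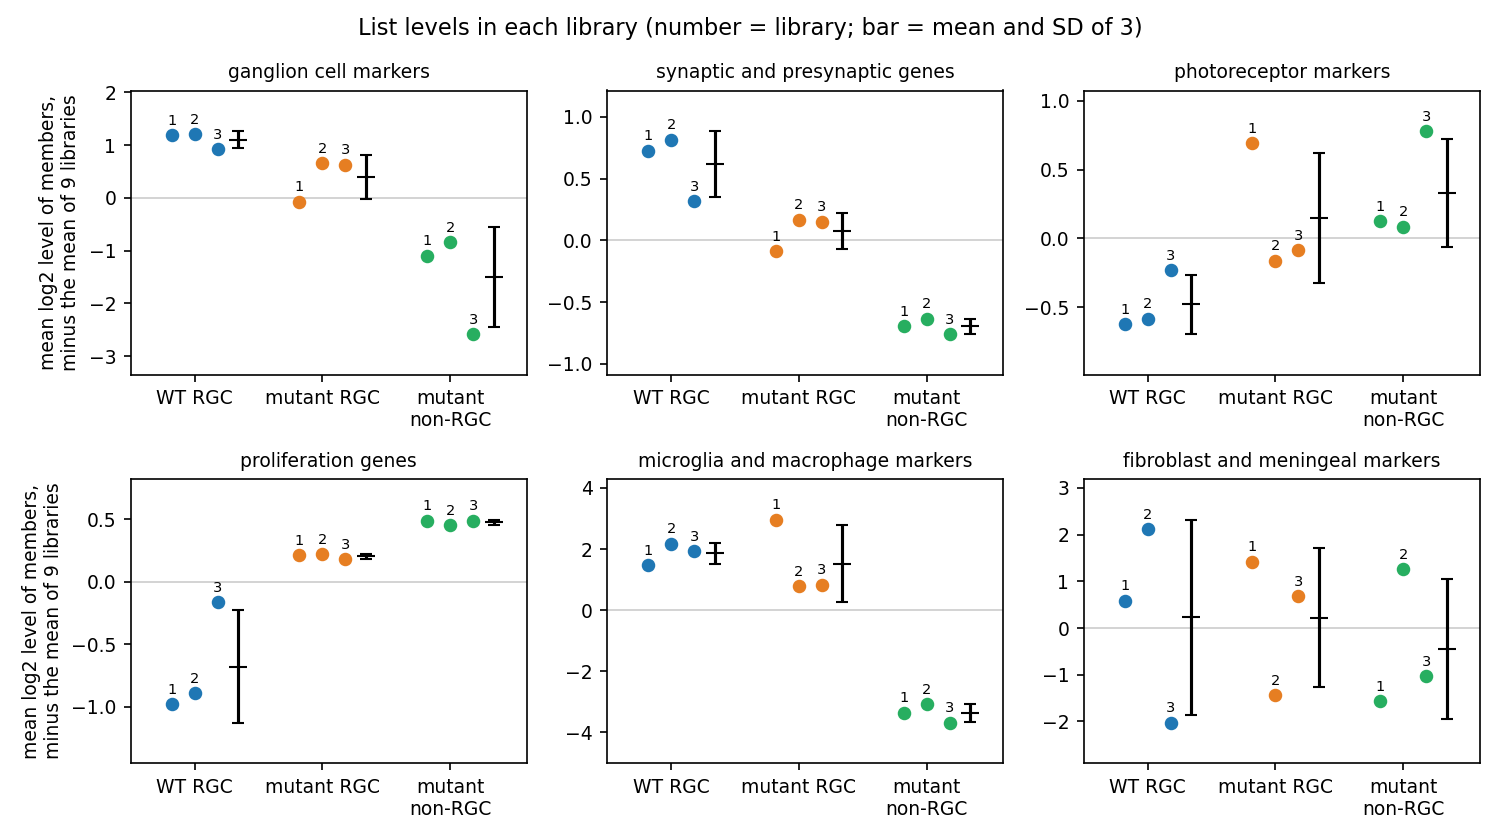
Mean log2 level of the members of 6 gene lists in each of the 9 libraries, relative to the mean of the 9 libraries (y axis), by group (x axis). Points are libraries with their number, and the bars beside them give the mean and SD of 3. WT library 3 lies apart from WT libraries 1 and 2 in proliferation genes, and microglia markers lie between -3.689 and -3.087 in the non-RGC libraries.

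The comparison of the mutant fractions shows how the bead selection divided the cells. In the non-RGC libraries 15 of 16 microglia markers and 20 of 32 ganglion cell markers were lower, and 20 of 38 proliferation genes were higher. Camera called these lists at a preset correlation and none of them with an estimated correlation (adjusted p = 0.4848, 0.5619 and 0.2443). Of 15178 genes tested, 2590 changed at a limma adjusted p under 0.05, 770 higher and 1820 lower in non-RGC cells, and 42 of the former and 857 of the latter changed by more than 2-fold. The 2 groups did not overlap for 37.7% of the tested genes, where chance gives 10% on average over splits, and again a single split can lie far from it. Among 32 ganglion cell markers, 20 fell and none rose (28 adjusted over the list alone), with a median log2 fold change of -1.74 (camera adjusted p = 6.73e-12, and adjusted p = 0.5619 with an estimated correlation). Non-RGC library 3 had the lowest mean ganglion cell level, -2.584 on the log2 scale relative to the mean of the 9 libraries, against -1.095 and -0.837 in non-RGC libraries 1 and 2, and mutant RGC library 1 had -0.078 against 0.653 and 0.629 in the other mutant RGC libraries. Elavl4, which encodes a neuronal RNA-binding protein, fell from 1518 ± 317 in RGCs to 594 ± 33.8 (SD, n = 3 each; log2 -1.33, SE 0.15, limma adjusted p = 0.0065), Klf7 by 1.33 and Nefh by 1.29. The ganglion cell transcription factor gene Pou4f2 had 1556 ± 542 and 299 ± 250 (log2 -3.13, SE 1.03) and Thy1 1350.5 ± 319 and 198 ± 178 (log2 -3.76, SE 1.16), and neither passed (limma adjusted p = 0.0790 and 0.0653). Both genes were chosen after their values were seen. Of 37 synaptic genes 24 fell and none rose (28 adjusted over the list alone; median -0.59, camera adjusted p = 2.99e-13, and adjusted p = 0.2443 with an estimated correlation), with Syn2 at -2.27. Of 43 axon guidance and adhesion genes 15 fell and 1 rose (21 and 1 adjusted over the list alone; median -0.32, camera adjusted p = 1.16e-05, and adjusted p = 0.2443 with an estimated correlation), with Nrp2 at -1.65, Nrp1 at -0.93 and Sema6a at -0.80.

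Microglial transcripts showed the largest difference between the fractions. Of 16 microglia and macrophage markers, 15 fell and none rose (15 adjusted over the list alone), with a median log2 fold change of -5.40 (camera adjusted p = 8.08e-13, and adjusted p = 0.4848 with an estimated correlation). The exception was Cd68 at -0.19 (limma adjusted p = 0.8286). The 8 largest decreases under the naming rule were Cx3cr1, C1qc, P2ry12, Trem2 and Fcrls of this list and the leukocyte genes Laptm5, Ctss and Emr1. The fractalkine receptor gene Cx3cr1 fell from 614 ± 604 to 2.05 ± 0.0676 (SD, n = 3 each; log2 -7.21, SE 0.61, limma adjusted p = 0.0042) and the complement gene C1qc from 488 ± 282 to 4.45 ± 1.26 (log2 -6.37, SE 0.41). The log2 fold changes of Laptm5, the protease gene Ctss and Fcrls were -6.65, -6.30 and -6.27. P2ry12 and Trem2 had 203 ± 208 and 134 ± 112 in RGCs and 0.336 ± 0.581 each in non-RGC cells, and Emr1 had 221 ± 265 in RGCs and no read in the non-RGC libraries. WT RGCs held these transcripts too, with Cx3cr1 between 424 and 580 normalised counts on the scale of all 9 libraries. Mutant RGC library 1 had the highest mean microglia level of the 9 libraries, 2.964 on the log2 scale against 0.775 and 0.823 in the other mutant RGC libraries.

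Genes higher in non-RGC cells changed by smaller amounts. Of 38 proliferation genes, 20 rose and none fell (35 adjusted over the list alone; median 0.26, camera adjusted p = 3.29e-15, and adjusted p = 0.2443 with an estimated correlation), with the mitotic kinesin gene Kif23 at 0.42, E2f1 at 0.37 and Aurka at 0.36. Of 32 progenitor and Mueller glia markers 6 rose and 1 fell (the same numbers adjusted over the list alone; median 0.19, camera adjusted p = 5.82e-06, and adjusted p = 0.2443 with an estimated correlation). The Notch effector genes Hes5 and Hes1 rose by 0.55 and 0.42, and Clu, which encodes the secreted chaperone clusterin, fell by 1.08. The histone list was higher by camera (median 0.40, adjusted p = 0.0057, and adjusted p = 0.5619 with an estimated correlation), though none of its 20 tested members passed singly and the call was lost without mutant RGC library 1 (adjusted p = 0.0527). Of 28 photoreceptor markers, 1 was higher (Gnb3 at 0.51) and 1 lower (Rxrg at -0.52), none adjusted over the list alone, and camera did not call the list (adjusted p = 0.0941). Mutant RGC library 1 and non-RGC library 3 had the highest photoreceptor levels, 0.693 and 0.779, against -0.162 and -0.085 in the other RGC libraries and 0.125 and 0.085 in the other non-RGC libraries. Without this pair of libraries, chosen after the data were seen, 13 markers were higher and 1 lower in non-RGC cells (median 0.18, camera adjusted p = 0.0011, and adjusted p = 0.4881 with an estimated correlation). Among amacrine markers, the calretinin gene Calb2 fell by 1.52, Ebf2 by 1.95 and Gad2 rose by 0.27 (camera adjusted p = 0.5052). The lens crystallin gene Crybb1 had 59.0 ± 49.7 in RGCs and 1.34 ± 1.54 in non-RGC cells (SD, n = 3 each). The 8 largest increases under the naming rule were between 2.32-fold and 2.70-fold, in Zfp692, Ager, the meiotic genes Msh5 and Stag3, Metap1d, Ankle1, Adamts10 and Izumo4. Zfp692 rose from 168 ± 3.34 to 464 ± 102 (log2 1.43, SE 0.17, limma adjusted p = 0.0070) and Ankle1 from 183 ± 14.5 to 442 ± 38.1 (log2 1.26, SE 0.11).

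The authors' deposited table of the fractions called 1635 genes, 295 higher and 1340 lower in non-RGC cells. Of them, 1568 were called here, all 1568 in the same direction, again nearly assured by the shared means and size factors. Scaling moved the split of calls: 29.7% of the limma calls were higher with the authors' size factors and 47.8% of 3063 calls with total-count scaling. Limma called 595 genes without mutant RGC library 2, 621 without mutant RGC library 3, 438 without non-RGC library 1 and 1243 without non-RGC library 2.

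Many genes lower in mutant RGCs than in WT were also lower in non-RGC cells than in mutant RGCs. Across the 14905 genes tested in both comparisons, which are not independent replicates, Pearson's r between the 2 log2 fold changes was 0.433 and Spearman's rho 0.525. Both comparisons use the mutant RGC libraries, once as the test group and once as the reference, which by itself gives a negative correlation. In 20 simulations of unchanged groups, r averaged -0.511 and the covariance -0.049, against an observed covariance of 0.179. The simulated genes varied independently of each other. Real libraries did not: against the other libraries of its group, WT library 3 differed along the fraction difference with r = 0.39 and WT library 2 with r = -0.42. The simulations therefore show the sign that sharing gives, and not the range of r that chance could give. Of 1800 genes lower in mutant than WT RGCs, 794 were also lower in non-RGC cells, where 219.2 would be shared by independent lists. Of 2092 genes higher in mutants, 227 were also higher in non-RGC cells against 107.4 for independent lists. Opposite calls numbered 57 (lower in mutants and higher in non-RGC cells, 92.4 for independent lists) and 4 (the reverse, 254.7 for independent lists). The 4 were Synrg, Zfp518b, Alg10b and Fam199x, named after their values were seen. With 3 shared libraries, the relation was not tested on separate sets of mutant RGC libraries. The correlation was 0.34 without WT library 2, 0.28 without mutant RGC library 2 and 0.31 without mutant RGC library 3.

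**Figure D3:**
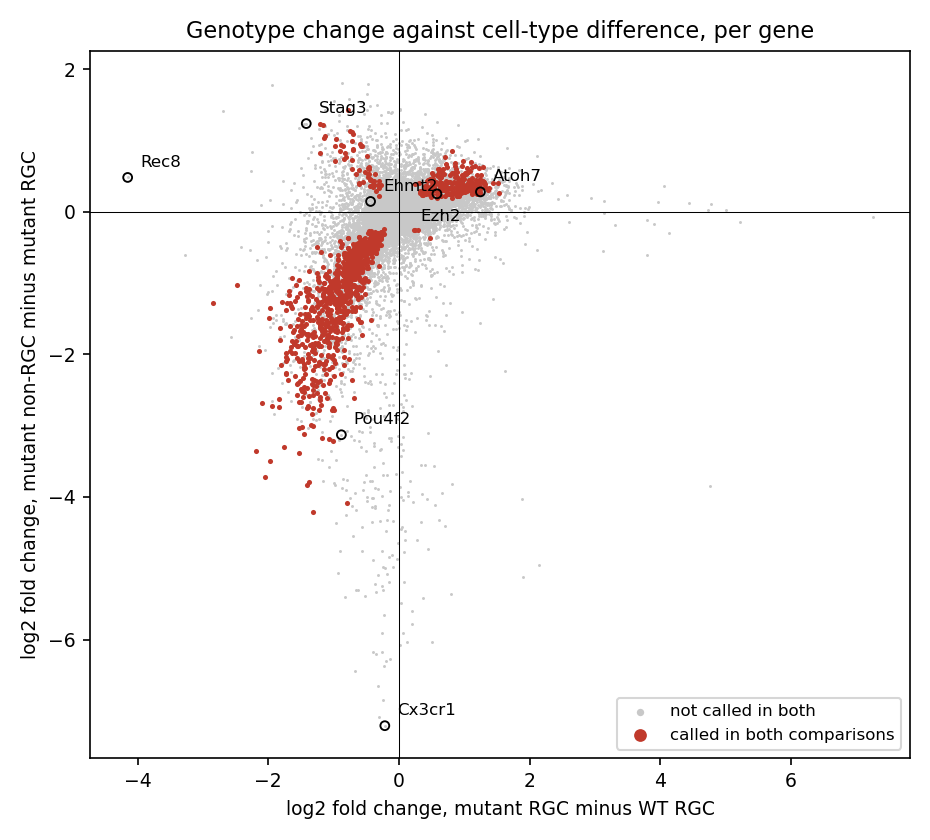
Each point is 1 of 14905 genes, with its log2 fold change between mutant and WT RGCs on the x axis and between mutant non-RGC and mutant RGC libraries on the y axis. Red points were called in both comparisons, most of them in the lower left (794 genes) and upper right (227 genes), while Rec8 and Cx3cr1 lie near a single axis.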

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

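The authors' calls, voom, upper-quartile and total-count scaling and the fits without pairs of libraries were added after the data were seen. Both gene counts stayed within 1.5 times with pseudocounts of 0.5 and 5, with no filter, with a mean of at least 50, with voom (4173 and 2192 genes) and under each scaling. The genotype count was 10 at an adjusted p under 0.01, 1122 with an absolute log2 fold change above 1, and 9059 without WT RGC library 3 and mutant RGC library 1. The count for the fractions was 397, 899 and, without mutant RGC library 1 and mutant non-RGC library 3, 6339. It was 1635 by the authors' calls, also with their Benjamini-Hochberg values recomputed, which are identical. Leaving out 1 library gave between 3 and 6478 genes for the genotypes and between 438 and 3325 for the fractions. The cause of these swings was not tested. Every gene called with all libraries and still tested kept its direction in each of these fits. The fits reuse the libraries on which the genes were called, so a kept direction was nearly assured and is no further support. Leaving out 1 library moved the log2 fold change of Ezh2 between 0.50 and 0.73 and of Ehmt2 between -0.51 and -0.32, and ended both calls in most of these fits. Called lists numbered 9 and 7 and fell to 0 and 0 with an estimated correlation per list, and lay between 6 and 10 and between 7 and 9 with 1 library left out; they numbered 8 and 10 without the pairs of libraries named above. Spearman in place of Pearson moved the relation of the comparisons to 0.525, and leaving out 1 library gave between 0.28 and 0.47. Of the named genes and called lists, 1 changed direction in any setting run: Atoh7 between the fractions, not called, was at -0.023 without mutant RGC replicate 1. Calls of named genes were lost in 398 of 771 fits with 1 library left out and in 24 of 126 by the authors' values. With a mean of at least 50, the astrocyte list and the histone list lost their calls. Genes under a mean of 10, such as the Hox genes, were not tested, and whether depth or lack of expression kept them low was not examined. No paired analysis was possible because the recovered libraries carry no sample numbers. Tests written for deposited count tables were not run.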

Other observations

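All tests of explanations in this part were chosen after the results were seen. Some gene groups had no place above. The pigment epithelium markers Pmel, Dct and Ttr were higher in mutant RGCs (log2 1.17, 1.11 and 1.08, limma adjusted p between 0.0396 and 0.0419), while Best1 was lower (log2 -0.95). Camera did not call this list (adjusted p = 0.3679). The horizontal cell genes Lhx1 and Prox1 were higher (log2 1.40 and 0.74) and Ret, a receptor gene, was lower (log2 -0.95), and camera did not call their list (adjusted p = 0.8479). Ifit2, an interferon-induced gene, rose by 0.62 and Irf9 fell by 0.46, without a call for the list (adjusted p = 0.7485). Best1 and Col3a1, and the genes of the next paragraph, were chosen after their values were seen. Genes of fibroblasts varied widely inside each group, with Col3a1 between 67.3 and 4930 normalised counts over the 9 libraries.

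The libraries were not alike in sex-linked genes. Mutant RGC library 1 had 4 reads of Xist, the RNA of the inactive X chromosome, and mutant non-RGC library 3 had 7. These 2 libraries had the most reads of the Y-linked Ddx3y, 811 and 752. The others had between 1179 and 9430 reads of Xist together with between 191 and 547 of Ddx3y, as pools of both sexes would. Pou4f2 had 24 reads in mutant non-RGC library 3 and 354 and 513 in the others of that group. Library 1 of the mutant RGCs stood apart on the second principal component of the 9 libraries (65.4, others between -25.9 and 4.3), which held 12% of the variance.

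The 57 genes lower in mutants but higher in non-RGC cells included Stag3, Adamts10 and Zfp692. No explanation was tested for them.

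With 3 libraries against 3, the 10 possible splits are too few for a share under 0.05. Only 1 split, the real one, gave as many genes for the genotypes (3971, next highest 1) and 1 for the fractions (2590, next highest 0). For the lists, 9 of the 10 splits called at least the real 9 lists in the genotype comparison (highest other 12), and 8 of 10 called at least the real 7 for the fractions (highest other 16). None of the lists was called with an estimated correlation in the real split.

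The first pattern weighed is the fall of ganglion and synaptic genes with the rise of proliferation, progenitor and photoreceptor genes in mutant RGCs. A larger share of non-ganglion retinal cells in the mutant RGC libraries is a candidate explanation. The position of mutant RGCs on the way from WT RGC to mutant non-RGC levels had medians of 0.68, 0.72, 0.77 and 0.64 for proliferation, progenitor, photoreceptor and amacrine genes. Their gap was 0.12, against a mean interquartile range of 0.16. That bar is easily met, since it sets medians of 12 to 37 genes against the spread of single genes. WT levels also enter both parts of each position, so a difference of both mutant fractions from WT would raise it too. The gap therefore cannot decide for this explanation. As the whole cause of the lower ganglion cell genes, a larger share predicts the same median for them, within the SD of their list. That prediction was not met, since their median of 0.51 lay below the others (difference -0.19, SD of the list 0.12). This is a smaller fall than such a share would give, while synaptic genes stood at 0.64 and axon guidance genes at 0.56. Duplicate removal compresses changes of short abundant transcripts, and its effect on these medians was not tested. Whether a larger share is the whole cause therefore stays open. Dilution of all bead-selected cells alike stays open too. Microglia markers stood at 0.05 and lay 1.48 above the log2 change of -1.73 that the share of the other lists needs (SD between libraries 0.92). Without mutant RGC library 1, the microglia change of -1.01 lay 0.02 above the -1.03 that the ganglion cell share needs. That share still included library 1, which had the lowest ganglion cell level of the mutant RGCs. The near match therefore cannot decide the question. Preparation differences may add to the pattern, since WT library 3 differed from the other WT libraries along the difference of the fractions. The correlation was r = 0.39 across 15043 genes, in libraries that share no sample. Its proliferation genes were 0.74 higher and its ganglion cell genes 0.26 lower (difference -0.26). The genotype, through fewer or less mature ganglion cells, stays open and untested, since WT non-RGC libraries were not analysed here.

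The second pattern is the set of 20 genes called more than 8-fold apart between mutant and WT RGCs, 16 of them higher in mutants and 16 with names of predicted genes, pseudogenes or related sequences. For genes 8-fold higher in mutants, a larger share of non-ganglion cells needs a further log2 rise of 0.46 from mutant RGC to non-RGC libraries. For genes lower in mutants, a share of 0.7, the median over the 4 other lists, could not give an 8-fold fall at all. The median further change in the same direction over the 18 genes tested between the fractions was -0.04 (SD 0.31), which argues against this explanation. The genes were chosen as extreme in the mutant RGC libraries, the reference of this change, which biases it downward. A strain difference between C57BL/6 WT and the mutants, the same in every cell type, could account for levels that match in both mutant fractions, with an SD of 0.31 in log2 and none of the 18 called between them. Nnt, in which the C57BL/6J substrain is known to carry a deletion (the labels give no substrain), was 2.62-fold higher in mutants (log2 1.39, limma adjusted p = 0.0057) and differed little between the fractions (log2 0.12, limma adjusted p = 0.2862). Reads shared with near-identical copies, and an effect of the genotype itself, stay open and untested, since strain and genotype change together here.

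The third pattern is the microglial signal in the bead-selected cells. Expression of these genes by ganglion cells was argued against, as their median fall between the fractions was larger than that of ganglion cell markers (log2 difference -3.66, SD of the ganglion list 1.24). Microglia kept with the bead-selected cells whatever the genotype is a candidate explanation, because mutant and WT RGCs differed by a median of -0.25 (SD 0.27), or -1.01 (SD 0.31) without mutant RGC library 1, where the fractions differed by -5.40, or -4.81 without it. Csf1r, an abundant member of the list, had between 456 and 2003 normalised counts in the 6 RGC libraries and between 7.70 and 14.5 in non-RGC cells. The labels name a selection for CD90 and no step against microglia, and whether the beads, the antibody or the column held these cells was not tested.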
